A study of Mus musculus with 18 samples.

How the data were processed

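RNA of sorted regulatory T cells from NOD mice was measured on 18 Affymetrix Mouse Gene 1.0 ST arrays, 1 per sample, in 6 groups of 3. Per the labels, RNA was extracted with TriZol and labelled with biotin using the Affymetrix WT Terminal Labeling kit. Spleen cells came from female mice and a FACSAria sorter, thymus cells from male mice and a MoFlo sorter, so sex, sorter, tissue and age cannot be separated between spleen and thymus, and each comparison was first made within a tissue. The series text describes a further arm with chimeras, of which the deposited table holds no arrays, and which is not analysed here. The labels do not say whether replicates are separate animals or pools, so p-values measure only the spread between samples.

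The deposited values are probe set intensities on the linear scale, as the range of 6.81 to 18850 shows. The authors made them with Affymetrix Power Tools and RMA, per the submitters' processing notes, which give no versions, no genome build, and no list of the arrays normalized together. For that reason no genome positions are given. Arrays have no read depth, and their number limits the precision.

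The table held 24922 probe sets, of which 21425 carry 1 gene symbol, 1399 several and 2098 none. By Entrez ID 21347 were found in the RefSeq gene table, which changed 0 symbols. One probe set per gene was kept, that with the highest mean, which gave 19752 genes (921 of them with more than 1 probe set). Values were log2 transformed with no pseudocount (0 values lay below 1) and not normalized again. A gene entered a fit when its mean in at least 1 group reached the median of all deposited values, 132.7 on the linear scale (7.052 on the log2 scale). That left 10350 genes in the spleen fit (12 arrays, 8 residual degrees of freedom, prior 6.76), 10650 in the thymus fit (6 arrays, 4 residual, prior 4.13) and 10889 in the fit of all 18 arrays (12 residual, prior 6.44).

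Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient per group, two-sided moderated test), with Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05. There were 7 contrasts: tagged perinate against adult, untagged perinate-treated against adult-treated, the difference between these differences, tagged against untagged in either treatment, perinate against adult thymus, and the spleen difference minus the thymus difference. The overlap of the spleen and thymus calls was tested per direction with a one-sided Fisher's exact test over the genes in both fits. With 3 arrays against 3, an exact permutation test of a single gene reaches no p below 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

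Fixed before the data were examined were the contrasts, the filter, 23 gene lists, the alternatives and the rule for naming genes. The rule takes, per contrast, genes past 0.05 whose groups do not overlap (not asked of interactions), up to 12 higher and 12 lower by size, after leaving out predicted genes and small RNAs. With fewer than 10 such genes it takes the lowest p up to 10, and it adds list members past 0.05 (up to 4 per list) and the check genes Foxp3, Il2ra, Ctla4, Ikzf2, Xist, Ddx3y and Eif2s3y. Lists were tested with camera at a preset correlation of 0.01, adjusted over 156 tests of lists with at least 3 measured members. Of these 65 passed, 0 with an estimated correlation and 45 by fry, which tests whether a list's genes move one way on balance and does not compare the list with other genes. Not all listed genes are on the array: 39 of 56 ribosomal protein genes, 20 of 25 cholesterol synthesis genes and 4 of 5 sex-linked genes are, for example.

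The code was tested on simulated data with known changes. The noise was normal and independent for each gene, with no hidden structure of the samples, so the error rates need not hold for the real arrays. For the spleen comparison (10350 genes) it recovered 89 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2, with 6 unchanged genes called (3.08% of calls). For the thymus comparison (10650 genes) it recovered 72 and 99 of 100, with 8 unchanged genes called (4.47%).

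The replicate numbers were checked for pairing by correlating the deviations of same-numbered arrays from their group means. The untagged arrays with numbers 3, 4 and 5 gave r of 0.63, 0.14 and 0.47, each over 0.1, the bound set for pairing, so these numbers were taken to pair the arrays. Perinate-treated replicate 4 correlated better with adult-treated replicate 5 (0.27), and adult-treated replicate 4 with perinate-treated replicate 5 (0.30). This is a pairing that comes from the data and not from the labels, and the blocked result stands beside that comparison. Alternatives covered quantile normalization, median centring, the filter, several probe sets of a gene, the variance prior, array weights, the arrays in the fit, pairing, a minimum 2-fold change and leaving out each array. Added after seeing the data were a filter at 240, the interquartile range of each array as a covariate, a block over all spleen arrays, and the omission of the arrays with the narrowest range.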

Results

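The data are 18 whole-transcript microarrays of regulatory T cells (Tregs), the CD4+ cells that carry the transcription factor Foxp3 and restrain immune responses, from NOD mice, a strain that develops autoimmune diabetes. They fall into 6 groups of 3 arrays. In 4 groups the cells came from the spleens of female mice at 60 days of age, per the labels. These mice carried a Foxp3-driven, tamoxifen-activated recombinase with a GFP tag and a YFP reporter, so that a cell expressing Foxp3 during tamoxifen treatment, and its descendants, stay YFP+. Tamoxifen was injected 4 times, between days 0 and 10 (perinate) or days 35 and 45 (adult). GFP+YFP+ cells (tagged) and GFP+YFP- cells (the untagged bulk) were sorted after each treatment. The other 6 arrays hold GFP+ thymic Tregs of male mice, aged 4 days (perinate thymus) or 5 weeks (adult thymus). Values are intensities on a log2 scale unless stated, each group has n = 3, and differences are log2 with their standard error (SE). The number of arrays limits the precision.

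Foxp3, the gene behind the GFP gate, was present in each group. Its mean was 11.95 ± 0.04 (SD) in perinate-tagged and 12.25 ± 0.11 in adult-tagged cells, and 12.19 ± 0.04 and 12.08 ± 0.19 in the untagged cells of perinate-treated and adult-treated mice. In perinate and adult thymus it was 12.37 ± 0.05 and 12.19 ± 0.20. The spread of values on an array, as the interquartile range of its log2 intensities, differed between groups: 3.05 ± 0.09 (SD) in perinate-tagged and 2.65 ± 0.21 in adult-tagged arrays. It was 2.95 ± 0.07 and 2.77 ± 0.28 in the untagged arrays, and 3.03 ± 0.03 and 2.53 ± 0.39 in perinate and adult thymus. One array did not match its label: perinate-tagged replicate 2, labelled female, had the Y-linked gene Eif2s3y at 9.79, against 3.95 to 4.90 on the 11 other spleen arrays, and Xist, the RNA of the inactive X chromosome, at 8.38, against 11.86 to 12.41.

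**Figure D1:**
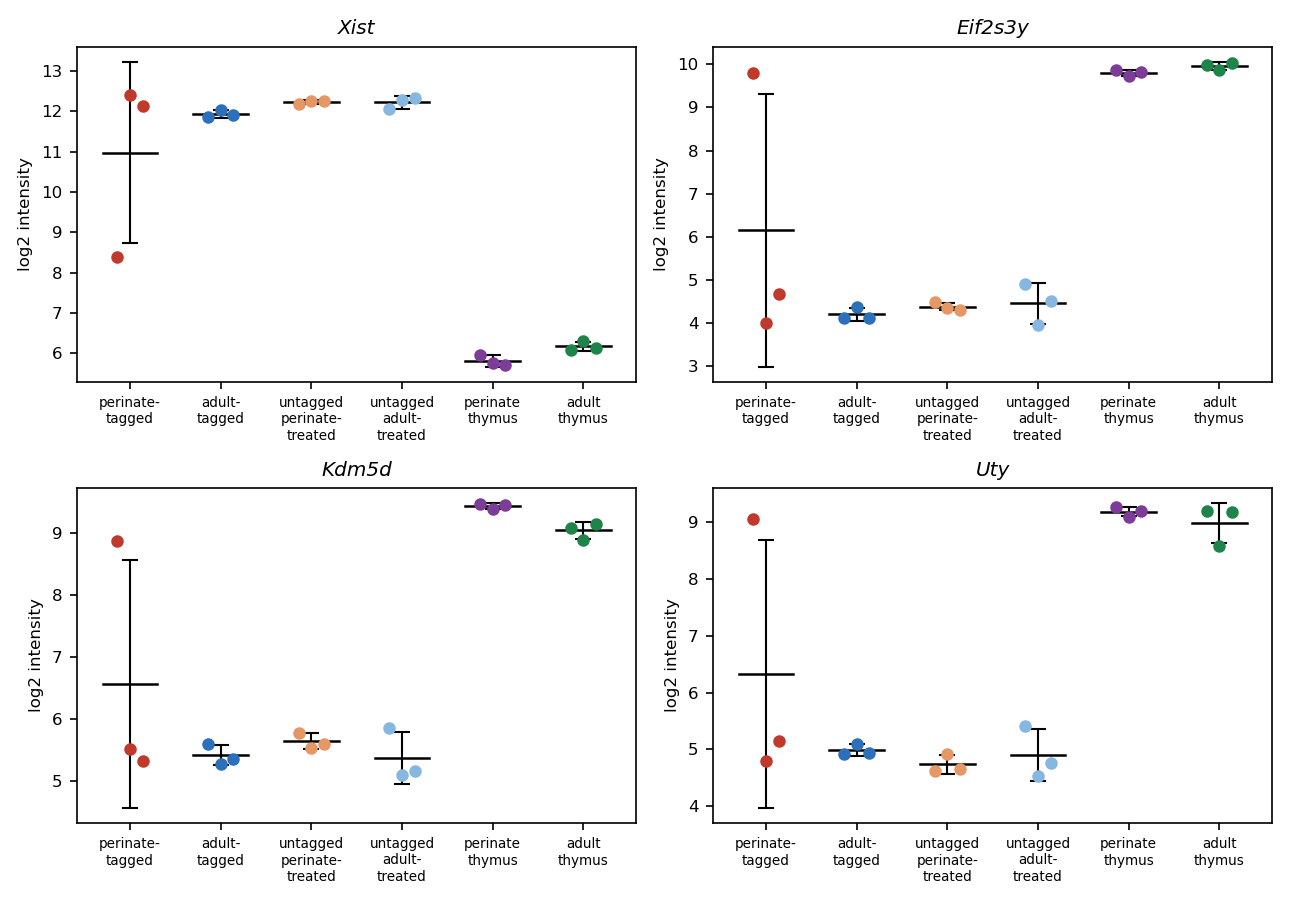
Log2 intensity of Xist and of the Y-linked genes Eif2s3y, Kdm5d and Uty on each of the 18 arrays, by group, with points for arrays and bars for the mean and SD. One perinate-tagged array lies at 8.38 for Xist and 9.79 for Eif2s3y, apart from the other 11 spleen arrays.

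The first comparison asked whether Tregs that arose around birth and persisted into adult life differ from Tregs tagged in the adult, at the same age and in the same organ. Perinate-tagged cells had far more transcript of genes of activated, tissue-homing Tregs and of dividing cells. Gzmb (probe set 10420308), a serine protease of cytotoxic granules, was 18.1-fold higher (4.18 ± 0.45, adjusted p = 1.84e-05), with a mean linear intensity of 2920 ± 277 (SD) against 171 ± 67.1. Klrg1 (10547590), a surface receptor of terminally differentiated T cells, was 14.5-fold higher (3.86 ± 0.47, adjusted p = 5.73e-05). Mki67 (10568714), the proliferation antigen Ki-67, was 6.29-fold higher (2.65 ± 0.22, adjusted p = 2.82e-06). Igf2bp3 (10544610), an RNA-binding protein best known from fetal tissues, was 5.80-fold higher or more (2.54 ± 0.17, adjusted p = 1.52e-06), at 303 ± 64.2 (SD) against 51.9 ± 9.06, a level not shown to lie above background. Untagged Tregs of the perinate-treated mice, the background for these genes, had linear means of 491 ± 293 for Gzmb, 355 ± 198 for Klrg1, 794 ± 195 for Mki67 and 63.2 ± 6.63 for Igf2bp3. Transcripts absent by sex (the Y-linked genes on the 11 female arrays, Xist on the 6 male arrays) read 3.95 to 6.3 on the log2 scale, which serves here as the level of background. A difference from a group mean in that range is a lower bound. Such means were those of Igf2bp3 (5.68), Il10 (5.03), Fgl2 (6.12) and Bub1 (5.73) in adult-tagged cells, of Il23r (5.40) and Cpne4 (5.73) in perinate-tagged cells, and of Igf2bp3 (5.98 and 6.03) and Dsg2 (5.70 and 5.70) in the untagged cells of perinate-treated and adult-treated mice. Further group means in that range are not listed here. In the perinate thymus they were those of Casp4 (5.88), Ccr2 (5.79), Prdm1 (6.13), Il23r (5.08) and Il10 (5.17).

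Of 10350 genes tested, 2020 differed, 1658 higher and 362 lower in perinate-tagged cells, and 379 of them differed at least 2-fold (355 higher, 24 lower). The groups did not overlap for 1983 of the 2020 genes, and for 45.8% of all genes, where chance gives 10%. Among the most raised genes were Fgl2, a secreted suppressive molecule of Tregs (3.00 ± 0.36), Myadm (2.89 ± 0.26), the calcium-binding S100a6 (2.81 ± 0.24) and the kinesin Kif11 (2.60 ± 0.22). The cytokine gene Il10 (3.15 ± 0.72), the chemokine gene Ccl5 (3.13 ± 0.67) and Penk, the precursor of enkephalin peptides (2.99 ± 0.46), were higher too. Among the lower genes were Zbtb20, a zinc-finger repressor (-1.61 ± 0.18), the long noncoding RNA Lncpint (-1.58 ± 0.15), the IGF1 receptor gene Igf1r (-1.20 ± 0.18), and the receptor gene Il23r (-1.84 ± 0.37).

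The effector Treg list gathers genes of activated Tregs. Of its 39 measured members 33 were higher and 1 lower (35 and 1 adjusted over the list alone), with a median difference of 1.23 (camera adjusted p = 1.71e-16, and adjusted p = 0.306 with an estimated correlation). All 31 measured mitosis genes were higher (31 adjusted over the list alone), by a median of 1.98, Bub1 by 2.81 ± 0.35 and Nusap1 by 2.57 ± 0.23 (adjusted p = 1.71e-30, and adjusted p = 0.248 with an estimated correlation). The 32 DNA replication genes were likewise all higher (32 adjusted over the list alone), by a median of 1.1, the ribonucleotide reductase subunit Rrm2 by 2.27 ± 0.24 and thymidylate synthase Tyms by 1.60 ± 0.20 (adjusted p = 5.02e-21, and adjusted p = 0.241 with an estimated correlation). Genes of resting, recirculating Tregs went the other way: 5 of 25 were lower and 0 higher (6 lower adjusted over the list alone), among them the lymph-node homing receptor Ccr7 (-0.91 ± 0.16) and the survival factor Bcl2 (-0.89 ± 0.13). That list's median was -0.30 (adjusted p = 4.7e-06, and adjusted p = 0.61 with an estimated correlation). Chemokine receptor and homing genes were higher in 14 and lower in 2 of 28 cases (15 and 2 adjusted over the list alone), led by Cxcr6 (2.59 ± 0.30), Ccr3 (2.10 ± 0.21), the collagen-binding integrin Itga2 (2.04 ± 0.26) and Ccr2 (2.00 ± 0.15). Over the 28 genes the median was 0.42 (adjusted p = 0.00283, and adjusted p = 0.248 with an estimated correlation).

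Respiratory-chain genes made up a further raised group, 24 of 48 with 0 lower (30 adjusted over the list alone) and a median of 0.42, for example Ndufb6 at 0.89 ± 0.15 (adjusted p = 2.99e-06, and adjusted p = 0.674 with an estimated correlation). Interferon-response genes were higher in 10 of 31 cases (20 adjusted over the list alone), by a median of 0.69, for example Cmpk2 at 1.45 ± 0.35 (adjusted p = 0.00121, and adjusted p = 0.847 with an estimated correlation). That difference rests on 2 of the 3 arrays: the list averaged 10.27 and 10.21 on perinate-tagged replicates 4 and 5 but 8.56 on replicate 2, below the 8.71 to 8.96 of the adult-tagged arrays. Its median was 1.188 without replicate 2, 0.504 without replicate 5, and 0.495 without replicate 4, where the list did not pass. Of 29 immediate early genes, which respond within minutes to stimulation or to cell handling, 8 were higher (13 adjusted over the list alone), Fos by 1.44 ± 0.25 and Ier3 by 1.09 ± 0.15. Over the 29 genes the median was 0.38 (adjusted p = 0.00428, and adjusted p = 0.786 with an estimated correlation). The myeloid marker list had 7 of 10 members higher (8 adjusted over the list alone). Over the 10 genes the median was 0.64 (adjusted p = 0.000616, and adjusted p = 0.363 with an estimated correlation). Its raised members, Ccr2, the oxidase subunit Cybb (1.62 ± 0.44), the haem oxygenase Hmox1 (0.93 ± 0.17) and the adhesion molecule Vcam1 (0.82 ± 0.23) among them, also occur in activated T cells or outside myeloid cells, while the abundant myeloid lysozyme Lyz2 had means of 6.10 and 6.28. Of 25 Treg identity genes 8 were higher and 2 lower (10 and 3 adjusted over the list alone), Ebi3, a subunit of the cytokine IL-35, by 1.88 ± 0.22, and the list as a whole did not pass (median 0.32, adjusted p = 0.291). The 11 measured fetal and imprinted genes held 4 higher and 1 lower member (4 and 1 adjusted over the list alone), and the list did not pass (median 0.01, below 0 with quantile normalization or median centring, adjusted p = 0.815). Foxp3 differed by -0.31 ± 0.12 (adjusted p = 0.0877) and Ctla4 by 0.53 ± 0.36 (adjusted p = 0.307).

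The median of all genes differed by 0.116 between the tagged groups, and quantile normalization and median centring moved it by -0.16 and -0.211, so that 2012 genes (1038 higher, 974 lower) and 2281 genes (913 higher, 1368 lower) passed. With the interquartile range of each array as a covariate 376 genes passed (305 higher, 71 lower), without Il10, Ccl5, Penk, Il23r, Fos, Cybb, Hmox1, Cmpk2, Ndufb6 and the immediate early list (median 0.09). The count was 906 without adult-tagged replicate 1, 1088 without adult-tagged replicate 3, 1075 without perinate-tagged replicate 4, 943 without perinate-tagged replicate 5 and 1986 without perinate-tagged replicate 2.

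**Figure D2:**
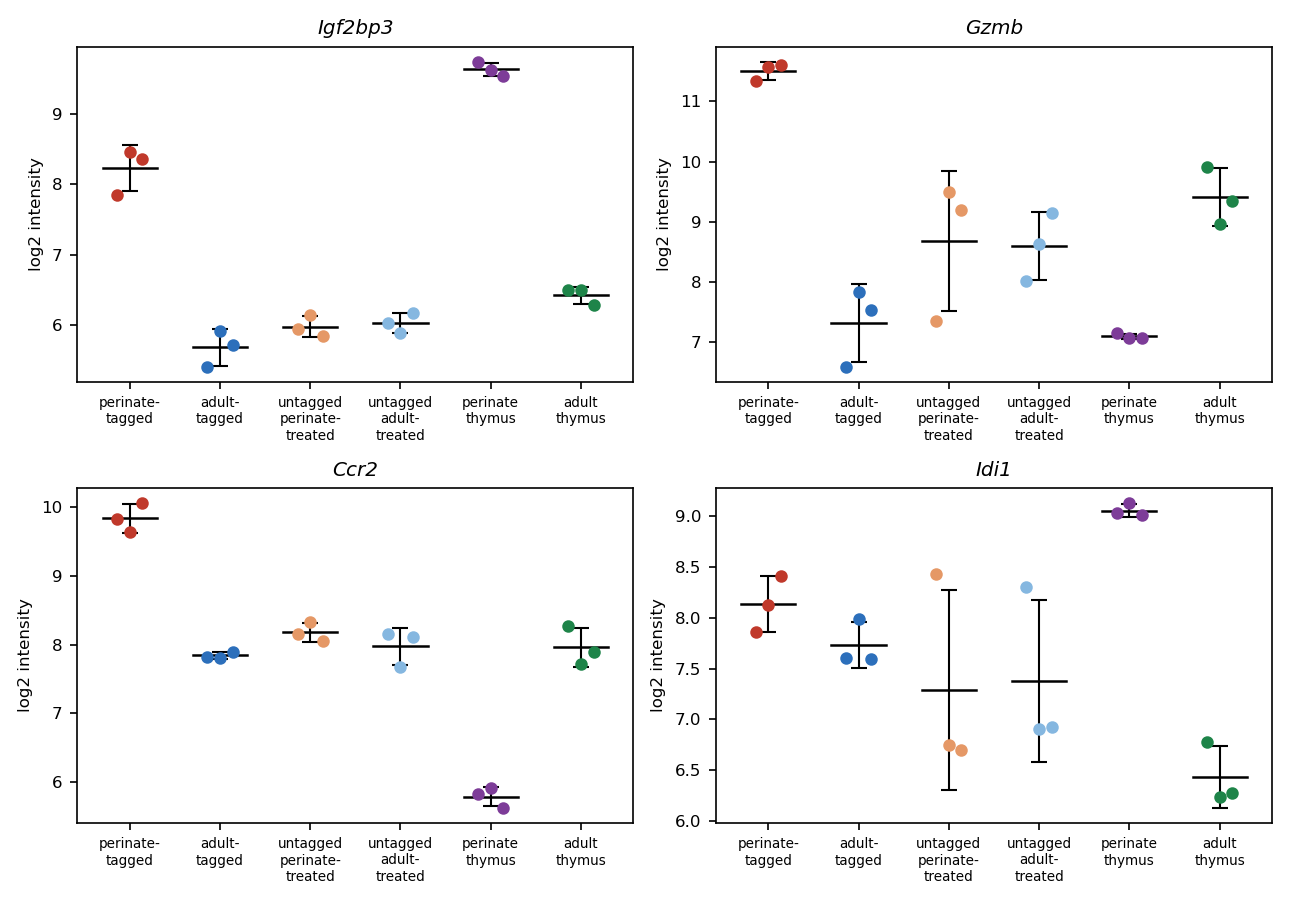
Log2 intensity of Igf2bp3, Gzmb, Ccr2 and Idi1 on each of the 18 arrays, by group, with points for arrays and bars for the mean and SD. Gzmb averaged 11.5 in perinate-tagged and 7.33 in adult-tagged spleen Tregs.

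**Figure D3:**
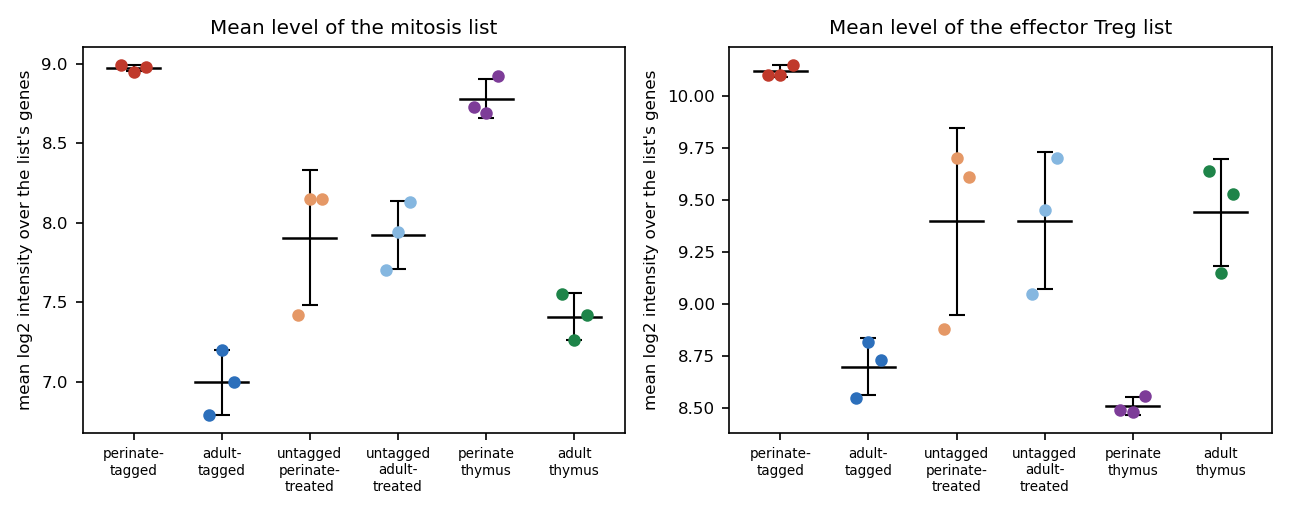
Mean log2 intensity of the mitosis and effector Treg lists on each of the 18 arrays, by group, with the mean and SD. The mitosis list averaged 8.97 in perinate-tagged cells, the highest of the 6 groups, with the untagged groups at 7.91 and 7.92.

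The untagged Tregs of the same treatments served as the background: they show what the age at tamoxifen treatment does outside the tagged cells, beside whatever else differs between these arrays. The median of 51 small nucleolar RNA genes, which can follow the recovery of RNA, was one such difference, at 8.66 to 9.53 after perinate and 8.17 to 8.64 after adult treatment (means 9.07 and 8.39), and its part in this contrast and in the interaction built on it was not tested. No gene differed between the untagged cells of perinate-treated and adult-treated mice. The limma count was 0 of 10350, with 380 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.995, and it was also 0 with a trended, robust prior and with array weights. Gzmb differed by 0.08 ± 0.45 and Foxp3 by 0.11 ± 0.12. Igf2bp3 read at the level of background in both groups, so its difference is not informative. The mitosis list averaged 7.91 ± 0.42 (SD) and 7.92 ± 0.21, and the effector Treg list 9.40 ± 0.45 and 9.40 ± 0.33. None of the 4 genes Endog, Aurkc, Ptgir and Mlycd, among those with the lowest p, passed (0.47 ± 0.12, -0.44 ± 0.12, 0.42 ± 0.12 and 0.53 ± 0.15). Among the lists, 3 passed the camera test with no member past the threshold in either count (0 over all genes, 0 adjusted over the list alone). The TCR and NF-kB activation list had a median of 0.11 (adjusted p = 0.0175, and adjusted p = 0.799 with an estimated correlation). The mitosis list had a median of 0.00 and a mean of -0.01 (adjusted p = 0.0404, and adjusted p = 0.864 with an estimated correlation), and stroma and epithelium genes had a median of -0.03 (adjusted p = 0.027, and adjusted p = 0.61 with an estimated correlation). The replicate numbers were taken to pair these arrays, although each replicate 4 correlated better with replicate 5 of the other treatment. With the number as a block 49 genes passed (37 higher, 12 lower), while a block over the 12 spleen arrays gave 0 in limma (562 genes at an unadjusted p under 0.05). Without untagged adult-treated replicate 3, 5 genes passed. Besides the estimated correlation, the stroma call was lost under 11 of 26 alternatives, the block among them, and turned under 1. The mitosis call was lost under 7 of 27, quantile normalization among them, and turned under 3, and the TCR and NF-kB call was lost under 6 of 27, the interquartile range as a covariate among them. Single arrays ended these calls too. The TCR and NF-kB list did not pass without untagged adult-treated replicates 3 or 4 or untagged perinate-treated replicates 4 or 5 (medians 0.128, 0.078, 0.096 and 0.09). The stroma list did not pass without untagged adult-treated replicates 3 or 4 or untagged perinate-treated replicate 4 (-0.016, -0.037 and 0.023). The mitosis list did not pass without untagged adult-treated replicates 4 or 5 (0.00 and 0.092), and its test turned to the higher side without untagged perinate-treated replicate 3 (0.221).

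The interaction asked whether the perinate against adult difference of tagged cells exceeded that of the untagged cells. It did so for effector and cell-cycle genes. The excess was 4.10 ± 0.63 for Gzmb (adjusted p = 0.00134), 3.74 ± 0.66 for Klrg1 (0.00355), 3.42 ± 0.37 for Myadm (0.000132) and 2.84 ± 0.31 for Mki67 (0.000132). For Igf2bp3 the value was 2.59 ± 0.24 (0.000132), but its adult-tagged and untagged means lay at the level of background. That value is therefore not exact, and it rests on the perinate-tagged arrays alone. Penk, Prr11, a gene active in mitosis, and Fgl2 had excesses of 3.21 ± 0.65, 3.19 ± 0.40 and 3.00 ± 0.51, and Ccr2 of 1.80 ± 0.21. On the lower side were Cpne4 (-1.90 ± 0.50), Zbtb20 (-1.57 ± 0.25), Lncpint (-1.51 ± 0.22), Igf1r (-1.47 ± 0.26), Als2cl (-1.42 ± 0.27) and the ganglioside synthase St8sia1 (-1.26 ± 0.34). In all 506 of 10350 genes passed, 444 with a positive and 62 with a negative difference of differences. Of the mitosis genes 30 of 31 passed (31 adjusted over the list alone; median 1.93, adjusted p = 4.67e-39, adjusted p = 0.241 with an estimated correlation), and of the effector Treg genes 19 of 39 (33 higher and 1 lower adjusted over the list alone; median 1.39, adjusted p = 1.96e-20, adjusted p = 0.271 with an estimated correlation). DNA replication genes passed in 24 of 32 cases (30 adjusted over the list alone). Over the 32 genes the median was 1.02 (adjusted p = 1.36e-23, and adjusted p = 0.241 with an estimated correlation).

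Quantile normalization gave 568 genes (409 higher, 159 lower) and median centring 539 (368 higher, 171 lower) for this interaction, and a block by replicate number over the 12 spleen arrays 274 (245 higher, 29 lower). The count was 279 without adult-tagged replicate 1, 332 without adult-tagged replicate 3, 311 without perinate-tagged replicate 4 and 307 without perinate-tagged replicate 5, and with both narrowest spleen arrays left out it was 247, without Klrg1, Penk and St8sia1.

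Within perinate-treated mice, tagged cells were compared with the untagged bulk of the same treatment, which holds Tregs that arose outside the tagging window. The median of the 51 small nucleolar RNA genes also differed between the tagged and untagged arrays without overlap, at 8.08 to 8.43 on the tagged and 8.66 to 9.53 on the untagged ones (means 8.31 and 9.07), and its part in the differences was not tested. The tagged cells were higher in Myadm by 3.17 ± 0.26 (adjusted p = 1.1e-05), in Gzmb by 2.82 ± 0.45 (adjusted p = 0.00167) and in Klrg1 by 2.55 ± 0.47 (adjusted p = 0.00431). Igf2bp3 was higher by 2.24 ± 0.17 (adjusted p = 8.04e-06), the leukotriene receptor Cysltr1 by 2.00 ± 0.16, the BMP receptor Bmpr1a by 1.95 ± 0.23 and the desmosomal cadherin Dsg2 by 1.91 ± 0.17. Lower in the tagged cells were Pik3ip1, an inhibitor of PI3 kinase (-1.47 ± 0.19), Igf1r (-1.36 ± 0.18), Lncpint (-1.32 ± 0.15) and the chemokine receptor Cxcr4 (-1.15 ± 0.22). In all 760 of 10350 genes differed, 568 higher and 192 lower. Of these, 752 had groups that did not overlap, as did 32.0% of all genes (10% by chance). Mitosis genes were higher in 27 of 31 cases (31 adjusted over the list alone; median 1.11, adjusted p = 9.1e-25, adjusted p = 0.28 with an estimated correlation) and DNA replication genes in 24 of 32 (29 adjusted over the list alone; median 0.68, adjusted p = 1.74e-20, adjusted p = 0.241 with an estimated correlation). The effector Treg list had 15 members higher and 1 lower of 39 (20 and 2 adjusted over the list alone). The untagged arrays were not alike in this list: it averaged 9.70 and 9.61 on untagged perinate-treated replicates 4 and 5 and 8.88 on replicate 3, against 10.1, 10.1 and 10.15 on the tagged arrays. Over the 39 genes the median was 0.48, and 0.323 and 0.657 without untagged perinate-treated replicates 3 and 4 (adjusted p = 4.1e-10, and adjusted p = 0.565 with an estimated correlation). Chemokine receptor and homing genes were higher in 9 and lower in 3 of 28 cases (11 and 3 adjusted over the list alone), the gut-homing receptor Gpr15 by 1.60 ± 0.14 and Ccr2 by 1.66 ± 0.15 (median 0.48, and 0.265 without untagged perinate-treated replicate 3, adjusted p = 0.000535, and adjusted p = 0.241 with an estimated correlation). Glycolysis genes were higher in 5 of 20 cases (7 adjusted over the list alone; median 0.19, adjusted p = 0.00266, adjusted p = 0.625 with an estimated correlation), Tpi1 by 0.82 ± 0.14 and Pgk1 by 0.72 ± 0.13.

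The myeloid list was also higher here, by a larger median than the effector Treg list, with 5 of 10 genes higher (6 adjusted over the list alone; median 0.72, adjusted p = 0.000111, adjusted p = 0.28 with an estimated correlation). Its raised members were Ccr2, the complement gene C1qb (1.18 ± 0.22), Vcam1 (0.96 ± 0.23), Hmox1 (0.75 ± 0.17) and the transcription factor Irf8 (0.75 ± 0.18), while Lyz2 had means of 6.10 and 5.84. Interferon-response genes were higher in 3 of 31 cases (3 adjusted over the list alone; median 0.67, adjusted p = 3.41e-05, adjusted p = 0.799 with an estimated correlation), again on perinate-tagged replicates 4 and 5 (median 1.107 without replicate 2, 0.37 without replicate 4 and 0.4 without replicate 5).

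Quantile normalization gave 975 genes (564 higher, 411 lower) and median centring 914 (563 higher, 351 lower) for this comparison. The count was 312 without perinate-tagged replicate 4, 299 without perinate-tagged replicate 5, 408 without untagged perinate-treated replicate 4 and 353 without untagged perinate-treated replicate 5.

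The matching comparison within adult-treated mice ran the other way, with few genes past the threshold. Tagged cells of adult-treated mice had less transcript of cell-cycle genes than the untagged bulk: Mki67 differed by -1.51 ± 0.22, Nusap1 by -1.47 ± 0.23, Kif11 by -1.43 ± 0.22 and Top2a, the topoisomerase of dividing cells, by -1.13 ± 0.18 (adjusted p = 0.0257 for each). In all 28 of 10350 genes differed, 0 higher and 28 lower (1699 had an unadjusted p under 0.05), and their groups did not overlap, as those of 17.0% of all genes (10% by chance). Of 31 mitosis genes 9 were lower (28 adjusted over the list alone). Over the 31 genes the median was -0.91 (adjusted p = 4.14e-28, and adjusted p = 0.248 with an estimated correlation). No effector Treg gene passed over all genes (0 of 39, against 26 lower adjusted over the list alone). Over the 39 genes the median was -0.67 (adjusted p = 2.69e-13, and adjusted p = 0.393 with an estimated correlation). Resting Treg genes passed in 0 of 25 cases (0 adjusted over the list alone) and had a median of 0.34, and of 0.196 without untagged adult-treated replicate 4 (adjusted p = 2.8e-06, and adjusted p = 0.61 with an estimated correlation).

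The count of 28 rests on single arrays: it was 0 without adult-tagged replicate 1, without adult-tagged replicate 3, without untagged adult-treated replicate 4 or without untagged adult-treated replicate 5, 774 without untagged adult-treated replicate 3 and 259 without untagged perinate-treated replicate 3. It was 13, 17, 10 and 16 without adult-tagged replicate 2, perinate-tagged replicate 2, perinate-tagged replicate 4 and perinate-tagged replicate 5, and 9 with quantile normalization, 12 with median centring and 0 with the interquartile range as a covariate.

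The thymus comparison asked how GFP+ Tregs in the newborn thymus differ from those in the thymus at 5 weeks. The gate does not show where the cells of either group arose. Perinate thymic Tregs had more transcript of cell-cycle, cholesterol-synthesis and ribosome-making genes and less of effector genes. Igf2bp3 was 9.27-fold higher (3.21 ± 0.12, adjusted p = 3.39e-05), with a mean linear intensity of 794 ± 52.8 (SD) against 85.7 ± 7.01. Idi1 (probe set 10482762), an enzyme of cholesterol synthesis, was 6.15-fold higher (2.62 ± 0.16, adjusted p = 0.000183). Cxcr3 (10606058), a chemokine receptor of type-1 effector cells, was 6.62-fold lower (-2.73 ± 0.17, adjusted p = 0.000183), with means of 6.90 ± 0.10 (SD) and 9.62 ± 0.33 on the log2 scale. Foxp3 differed by 0.18 ± 0.13 (adjusted p = 0.309).

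Of 10650 genes tested, 2589 differed, 1967 higher and 622 lower in the perinate thymus, and 435 differed at least 2-fold (324 higher, 111 lower). The groups of these genes did not overlap, as those of 53.6% of all genes (10% by chance). Other genes far higher in the perinate thymus were the ubiquitin ligase Nedd4 (2.42 ± 0.18), Btbd3 (2.28 ± 0.11), Ly86, a partner of a Toll-like receptor homologue (2.17 ± 0.21), and Top2a (2.10 ± 0.16). The class I histocompatibility gene H2-Q4 was higher by 3.01 ± 0.34 and the histone genes H1f1 and H4c6 by 2.25 ± 0.26 and 2.20 ± 0.38, although near-identical family members make these probe sets uncertain. Far lower were the inflammatory caspase Casp4 (-2.76 ± 0.15), Il23r (-2.57 ± 0.20), the decoy receptor Il1r2 (-2.25 ± 0.14) and Prdm1, a regulator of effector differentiation (-2.28 ± 0.13). Gzmb, Klrg1 and Ccr2, which were raised in perinate-tagged spleen cells, were lower here (-2.31 ± 0.22, -2.09 ± 0.31 and -2.17 ± 0.16).

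The mitosis list was higher in full, 31 of 31 (31 adjusted over the list alone), by a median of 1.39 (camera adjusted p = 3.16e-17, and adjusted p = 0.28 with an estimated correlation). DNA replication genes were higher in 28 of 32 cases (31 adjusted over the list alone), Mcm5 by 1.58 ± 0.15. Over the 32 genes the median was 1.06 (adjusted p = 7.88e-13, and adjusted p = 0.393 with an estimated correlation). Cholesterol synthesis stood out with 16 of 19 genes higher (17 adjusted over the list alone), Hmgcs1 by 1.68 ± 0.14 and Sqle by 1.64 ± 0.12. Over the 19 genes the median was 0.95 (adjusted p = 1.15e-07, and adjusted p = 0.583 with an estimated correlation). Ribosome biogenesis genes were higher in 21 of 31 cases (27 adjusted over the list alone), Nop58 by 1.36 ± 0.20. Over the 31 genes the median was 0.57 (adjusted p = 4.05e-07, and adjusted p = 0.596 with an estimated correlation). The effector Treg list fell on the other side, with 23 of 39 genes lower and 1 higher (23 and 1 adjusted over the list alone). Over the 39 genes the median was -0.96 (adjusted p = 1.9e-14, and adjusted p = 0.583 with an estimated correlation). Chemokine receptor and homing genes were lower in 12 of 26 cases (12 adjusted over the list alone), among them Cxcr6 (-1.97 ± 0.26) and Ccr4 (-1.73 ± 0.30). Over the 26 genes the median was -0.24, with -0.144 and -0.391 without adult thymus replicates 1 and 2 (adjusted p = 1.88e-05, and adjusted p = 0.674 with an estimated correlation). The myeloid list was lower in 3 of 8 cases, Ccr2, Cybb and C1qb (4 adjusted over the list alone). Over the 8 genes the median was -0.47 (adjusted p = 0.00032, and adjusted p = 0.306 with an estimated correlation).

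Smaller differences in the thymus were in genes of ribosomal proteins, higher in 14 of 39 cases (18 higher and 1 lower adjusted over the list alone). Over the 39 genes the median was 0.40 (adjusted p = 0.00806, and adjusted p = 0.847 with an estimated correlation). Glycolysis genes were higher in 10 of 21 cases (13 adjusted over the list alone). Over the 21 genes the median was 0.57 (adjusted p = 0.00697, and adjusted p = 0.805 with an estimated correlation). Respiratory-chain genes were higher in 13 of 48 cases (16 higher and 1 lower adjusted over the list alone). Over the 48 genes the median was 0.43 (adjusted p = 0.0101, and adjusted p = 0.847 with an estimated correlation). Interferon-response genes were lower in 6 of 31 cases (4 adjusted over the list alone), among them Iigp1 (-1.23 ± 0.11) and Rsad2 (-1.03 ± 0.18), although the list's median was 0.02, its mean -0.05 and its test on the lower side (adjusted p = 0.0437, and adjusted p = 0.847 with an estimated correlation). The interferon list did not pass under 8 of 17 alternatives, among them those without adult thymus replicates 1 or 3 or perinate thymus replicate 2 (medians 0.05, 0.063 and 0.014), and its median was -0.099 without adult thymus replicate 2. Of 29 immediate early genes 9 were higher and 4 lower (9 and 4 adjusted over the list alone), Fos by 1.67 ± 0.22 (median 0.49, adjusted p = 0.562). Of 14 fetal and imprinted genes 7 were higher (7 higher and 1 lower adjusted over the list alone; median 0.30, adjusted p = 0.141), Igf2bp3, Nedd4, the imprinted Peg3 (0.91 ± 0.18) and the mannose-6-phosphate receptor Igf2r (0.89 ± 0.17) among them.

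The median of all genes differed by 0.168 between the thymus groups, and quantile normalization and median centring moved it by -0.182 and -0.232, so that 2519 genes (1347 higher, 1172 lower) and 2809 genes (1178 higher, 1631 lower) passed. With the interquartile range as a covariate the ribosomal protein, respiratory-chain and glycolysis lists did not pass (medians 0.12, 0.11 and 0.17), and the count was 4388 without adult thymus replicate 1, 4199 without replicate 2 and 1019 without replicate 3 of that group, and 707, 807 and 787 without perinate thymus replicates 1, 2 and 3.

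The last contrast asked where the perinate against adult difference in the spleen departs from that in the thymus. Effector and homing genes were among those that departed. The spleen difference exceeded the thymus difference by 6.49 ± 0.60 for Gzmb (adjusted p = 1.45e-06), 5.95 ± 0.66 for Klrg1 (1.27e-05), 5.15 ± 0.95 for Il10 (0.00221), 4.61 ± 0.48 for Fgl2 (6.97e-06), 4.56 ± 0.44 for Cxcr6 (2.35e-06), 4.48 ± 0.71 for the inhibitory receptor Tigit (0.000605) and 4.17 ± 0.22 for Ccr2 (2.16e-09). It fell short of it for the cholesterol-synthesis genes Idi1 (-2.22 ± 0.53) and Sqle (-1.82 ± 0.41), for Qser1 (-2.26 ± 0.49), Btbd3 (-1.85 ± 0.21), Nedd4 (-1.82 ± 0.24), and H2-Q4 (-2.92 ± 0.48, uncertain as above). Mki67 differed by 1.01 ± 0.28 (adjusted p = 0.0383). In all 703 of 10889 genes passed, 424 on the spleen side and 279 on the thymus side. Effector Treg genes passed in 27 of 39 cases (34 adjusted over the list alone). Over the 39 genes the median was 2.05 (adjusted p = 2.74e-45, and adjusted p = 0.097 with an estimated correlation). Chemokine receptor and homing genes passed in 13 cases on the spleen side and 1 on the thymus side, of 28 (15 and 1 adjusted over the list alone; median 1.01, adjusted p = 3.26e-12, adjusted p = 0.097 with an estimated correlation). The myeloid list passed with 7 of 10 genes, Ccr2, Cybb (3.32 ± 0.59) and C1qb (1.78 ± 0.30) among them (9 adjusted over the list alone; median 1.17, adjusted p = 5.17e-11, adjusted p = 0.097 with an estimated correlation). Cholesterol synthesis had 7 of 19 genes on the thymus side (12 there and 1 on the spleen side adjusted over the list alone). Over the 19 genes the median was -0.84 (adjusted p = 3.08e-06, and adjusted p = 0.546 with an estimated correlation). Ribosome biogenesis had 6 of 31 there (15 adjusted over the list alone). Over the 31 genes the median was -0.50 (adjusted p = 1.89e-09, and adjusted p = 0.363 with an estimated correlation). The DNA replication list did not pass, with 2 genes on the spleen side and 1 on the thymus side of 32 (2 and 1 adjusted over the list alone; median -0.08, adjusted p = 0.988).

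Quantile normalization gave 1147 genes (590 on the spleen side, 557 on the thymus side), median centring 1082 (586 and 496) and the interquartile range as a covariate 1462 (818 and 644). The count was 461 without adult-tagged replicate 1, 461 without perinate-tagged replicate 5, 1069 without adult thymus replicate 1, 465 without adult thymus replicate 3, 393 without perinate thymus replicate 1 and 463 without perinate thymus replicate 2, and Mki67 did not pass without adult-tagged replicate 1, among others.

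Perinate-tagged spleen Tregs and perinate thymic Tregs also shared differences from their adult counterparts. Of 10111 genes tested in both tissues, 600 were higher in both, where independent lists would share 296 (one-sided Fisher's exact test, p = 2.27e-87), and 61 were lower in both, where 19.1 would be shared (p = 2.31e-16). This test takes genes as independent, which they are not, so its p-values here do not measure replication across samples. With quantile normalization 370 genes were higher and 207 lower in both (122 and 106 for independent lists). With median centring 321 were higher and 355 lower (96.1 and 199). Igf2bp3 (2.54 ± 0.17 in spleen, 3.21 ± 0.12 in thymus), Ly86 (1.73 ± 0.21 and 2.17 ± 0.21) and Kif11 (2.60 ± 0.22 and 2.01 ± 0.25) were higher in both, and Il23r (-1.84 ± 0.37 and -2.57 ± 0.20) was lower in both. Gzmb, Klrg1 and Ccr2 were higher in perinate-tagged spleen cells and lower in the perinate thymus, as 95 genes were (88.7 for independent lists, one-sided Fisher's exact test, p = 0.241). Whether 95 is an excess depends on single arrays. Without perinate thymus replicates 1, 2 and 3 there were 54, 58 and 59 such genes (29.9, 32.5 and 34.6 for independent lists, Fisher's exact test, p = 5.23e-06, 3.83e-06 and 1.5e-05), and without adult thymus replicate 3 there were 59 (36.9, p = 0.000107). Without adult-tagged replicates 1 and 3 there were 64 and 68 (41.5 and 51.5, Fisher's exact test, p = 0.000286 and 0.01), and without perinate-tagged replicates 4 and 5 there were 69 and 65 (49.6 and 45.6, p = 0.00276 and 0.00207). Without adult thymus replicate 2 it was 169 (216 for independent lists). A further 4 genes went the opposite way (63.9 for independent lists). Across genes, which are not independent replicates, the log2 differences of both tissues correlated with Pearson's r = 0.38 and Spearman's rho = 0.432. The untagged contrast, in which no gene passed, correlated with the thymus contrast with r = 0.308 and rho = 0.349. With the interquartile range as a covariate 166 genes were higher in both (29 for independent lists) and 32 lower (9.11), and r was 0.193 and rho 0.129. The count of 661 genes in one direction was 389 without adult-tagged replicate 1, 433 without adult-tagged replicate 3, 420 without perinate-tagged replicate 4, 387 without perinate-tagged replicate 5, 397 without adult thymus replicate 3, and 313, 335 and 313 without perinate thymus replicates 1, 2 and 3.

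**Figure D4:**
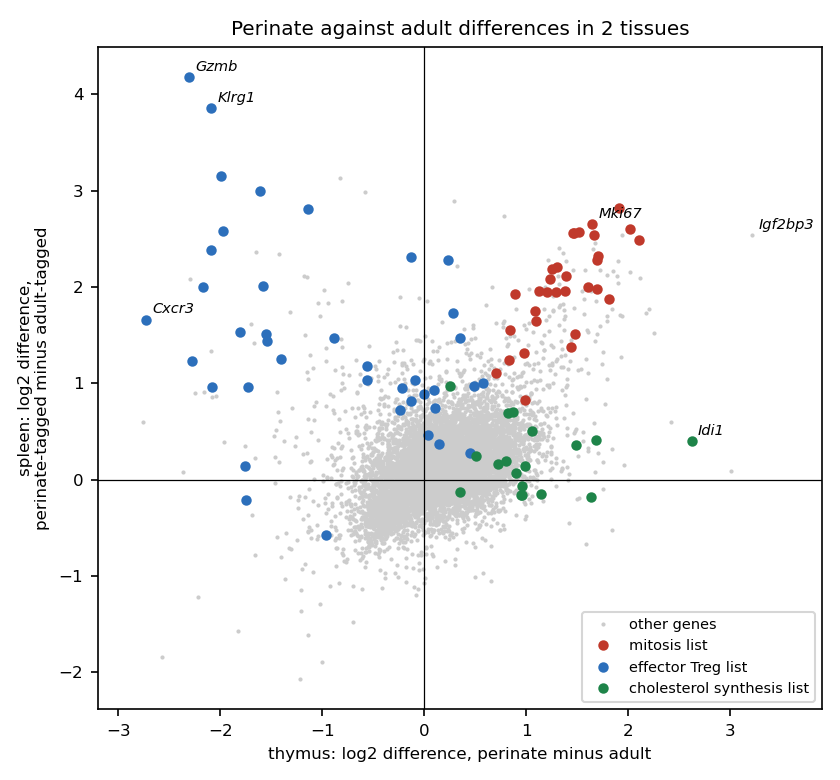
Log2 difference between perinate and adult thymic Tregs (x axis) against that between perinate-tagged and adult-tagged spleen Tregs (y axis), 1 point per gene tested in both, with the mitosis, effector Treg and cholesterol synthesis lists in colour. Igf2bp3 lies high on both axes (3.21 and 2.54), and Gzmb and Klrg1 lie low in thymus (-2.31 and -2.09) and high in spleen (4.18 and 3.86).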

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

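Of the tests in this part, those of the narrow range, the array with male levels, myeloid cells and cell-cycle genes were chosen only after the result was seen, and so were Mki67, Ccr2 and, in the tagged interaction, Igf2bp3 as single genes. The splits of the arrays were planned, while their comparison by pairs and by the arrays moved was chosen after the counts were seen.

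Results stand here because a test of the difference between effects passed. Between tagged and untagged spleen Tregs the perinate against adult difference differed for 506 genes. On the higher side were Gzmb (4.10), Klrg1 (3.74), Myadm (3.42), Penk (3.21), Prr11 (3.19), Fgl2 (3.00), Mki67 (2.84), Igf2bp3 (2.59) and Ccr2 (1.80). The value for Igf2bp3 is not exact, since its adult-tagged and untagged means lay at the level of background. On the lower side were Cpne4 (-1.90), Zbtb20 (-1.57), Lncpint (-1.51), Igf1r (-1.47), Als2cl (-1.42) and St8sia1 (-1.26). The lists that passed here, none of them with an estimated correlation, had medians of 1.93 (mitosis), 1.39 (effector Treg), 1.02 (DNA replication), 0.80 (myeloid), 0.68 (interferon response), 0.41 (chemokine receptors and homing), 0.32 (oxidative phosphorylation), 0.19 (immediate early genes), -0.14 (ribosomal proteins) and -0.30 (resting Treg). Of these, 4 lean on single arrays. In the interferon list 0 of 31 genes passed, and its mean was 10.27 and 10.21 on perinate-tagged replicates 4 and 5 but 8.56 on replicate 2. It did not pass without replicate 4 or 5 (0.42 and 0.445) or with a block over the 12 spleen arrays (0.261), and its median was 1.111 without replicate 2. The immediate early list did not pass without perinate-tagged replicates 4 or 5, untagged adult-treated replicate 5 or untagged perinate-treated replicate 3 (0.148, 0.154, 0.149 and 0.076), and was 0.308 without untagged adult-treated replicate 4. The ribosomal protein list did not pass without adult-tagged replicate 3 or untagged perinate-treated replicate 4 (-0.095 and -0.069), and was -0.087 and -0.077 without perinate-tagged replicate 2 and untagged adult-treated replicate 4. The resting Treg list was -0.14 and -0.494 without untagged perinate-treated replicates 3 and 4.

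Between spleen and thymus the perinate against adult difference differed for 703 genes. Gzmb (6.49), Klrg1 (5.95), Il10 (5.15), Fgl2 (4.61), Cxcr6 (4.56), Tigit (4.48), Ccr2 (4.17) and Mki67 (1.01) lay on the spleen side. H2-Q4 (-2.92), Qser1 (-2.26), Idi1 (-2.22), Btbd3 (-1.85), Sqle (-1.82) and Nedd4 (-1.82) lay on the thymus side. Lists that passed on the spleen side, again none with an estimated correlation, had medians of 2.05 (effector Treg), 1.17 (myeloid), 1.01 (chemokine receptors and homing), 0.83 (interferon response), 0.66 (mitosis), 0.40 (NK and cytotoxic), 0.24 (conventional CD4 T cell) and 0.10 (Treg identity). On the thymus side they were -0.84 (cholesterol synthesis), -0.50 (ribosome biogenesis), -0.45 (resting Treg), -0.44 (ribosomal proteins), -0.30 (fetal and imprinted genes) and -0.30 (glycolysis). The glycolysis list did not pass under 17 of 28 alternatives, 10 of which leave out 1 array (-0.138 without adult thymus replicate 2, for example). The NK list did not pass without perinate-tagged replicate 5 (0.366), the Treg identity list not without adult thymus replicate 1 (-0.036), and the fetal list not without adult thymus replicates 1 or 3 or perinate thymus replicate 2 (-0.319, -0.319 and -0.306). Other single arrays moved the Treg identity median too, though the list passed: it was 0.024 and 0.184 without adult-tagged replicates 1 and 2. Without adult thymus replicate 2 the fetal list was -0.476 and the resting Treg list -0.266, and without adult thymus replicate 1 the conventional CD4 list was 0.149. The interferon list was 1.258 and 0.541 without perinate-tagged replicates 2 and 4.

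Probe sets with no gene name or several, which the comparisons leave out, also differed: 206 of 1867 between the tagged groups (168 higher, 38 lower) and 319 of 1877 between the thymus groups (185 higher, 134 lower).

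The mitosis and effector Treg lists were higher in perinate-tagged than in adult-tagged cells, on arrays that also differed in the range of their values. With the interquartile range as a covariate the median of the mitosis list was 1.73 (quartiles 1.42 and 2.06) where it had been 1.98, and 29 of 31 genes passed. This argues against the narrow range as its whole cause, as far as a slope found within groups holds between them. The ranges of the tagged groups did not overlap. For the effector Treg list the median was 0.95 (quartiles 0.49 and 1.78) where it had been 1.23, and 16 of 39 genes passed where 33 had. For the 17 genes that no longer passed, the median difference went from 1.03 to 0.75 and the median SE from 0.24 to 0.3, so smaller differences and wider errors both ended calls, and the share of the range in this list stays open. Without the array with male levels of Y-linked genes 63 of the 64 raised members were still higher, which argues against that array as the cause. Myeloid cells in the sort stay open: Lyz2, Tyrobp, Fcer1g and Cst3 differed by a median of 0.16 but went both ways (-0.18, 0.12, 0.64 and 0.20), Lyz2 lay at the level of background, and the myeloid list was higher (7 of 10 genes, median 0.64, adjusted p = 0.000616). The time of tagging, and the different age since tagging that goes with it, remain untested explanations.

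Genes called in one direction in both spleen and thymus exceeded independent lists, and in both tissues the adult arrays had the narrower range. With the range as a covariate in both fits 166 genes were higher in both, where independent lists would share 29. This cannot exclude the range, which did not overlap between the groups. It was 2.94 to 3.12 against 2.49 to 2.88 in tagged arrays, and 3.00 to 3.06 against 2.08 to 2.82 in the thymus. The covariate thus carries a slope found within groups across a gap. In the thymus, 1878 genes were higher and 562 lower without the covariate, and 1040 and 1354 with it. The correlation across genes fell with the covariate, Pearson's r from 0.38 to 0.193 and Spearman's rho from 0.432 to 0.129. Without the DNA replication and mitosis lists 541 genes were higher in both (277 for independent lists), but these lists do not hold every gene of the cell cycle, so how much of the overlap reflects division stays open. A shared perinatal origin is a biological explanation that the design names and that was not tested.

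The splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. Only the real split of the tagged arrays, 1 of the 10, called as many as its 2020 genes, and the highest other split called 0. For tagged against untagged cells the real split called 760 (highest other 1) in perinate-treated and 28 (highest other 5) in adult-treated mice, and for the thymus 2589 (highest other 0). Every other split mixes the real groups, which puts a real difference into the spread within groups and lowers its count. The low counts of the other splits are therefore no evidence against chance. In the untagged comparison all 10 splits called at least the real 0, as any split must, so that tally tests nothing. The highest split called 1062. That split parted 1 of the 3 pairs of same-numbered arrays, but the other splits that parted 1 pair called 0. So did the splits that parted all 3 pairs, the real one among them. The number of pairs parted therefore does not account for the 1062 genes, which point to a structure of these samples other than the treatment. That split set untagged perinate-treated replicate 3 and untagged adult-treated replicates 3 and 4 against the other untagged arrays. On the first principal component of the spleen arrays the named arrays lay at -11.3, -12.7 and -8.2, and the others between 8.1 and 12.3. Their interquartile ranges were 2.88, 2.72 and 2.51, against 2.99 to 3.07 on the others. What this structure is was not tested.

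For the interactions and the overlap 100 splits were drawn. In 6 of them the tagged against untagged interaction called at least the real 506 genes (highest other 3792), so chance is not excluded there. The split with 3792 parted 1 pair of same-numbered untagged arrays, but another that parted 1 pair and left the tagged groups as they are called 354. The count of 3792 points to a structure of the samples. Among the 37 drawn splits that part all 3 untagged pairs, as the real one does, 2 called at least 506 (highest other 906). The 5 other splits that reached 506 left the tagged groups as they are and moved only untagged arrays, so the tagged difference was still in them, and they do not test whether that difference arose by chance. The 91 that moved tagged arrays called at most 1, but mixing the tagged groups widens their spread, so this does not test it either. For the spleen and thymus interaction 4 of 100 splits called at least the real 703 (highest other 4671). Moving arrays also breaks up the differences within each tissue, so these splits test for any difference and not for the interaction alone. Chance is therefore not excluded for it. The split with 4671 kept the tagged groups and exchanged perinate and adult thymus, which adds the effects of both tissues where the real split subtracts them. The other 2 that reached 703, with 2838 and 1244 genes, moved 2 arrays of each tagged group and no thymus array. Of the 91 splits that moved tagged arrays these 2 reached 703, and of the 8 that moved only thymus arrays 1 did. Whether a structure of the samples adds to these counts was not tested. The overlap of 661 genes was reached by 1 of 100 splits, the real one (highest other 0). Since no other split of the tagged or of the thymus arrays called a gene, the splits could not share calls, and this count does not test the overlap.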

How the results depend on the processing

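The filter at 240, the interquartile range as a covariate, the block over the 12 spleen arrays and the omission of the narrowest arrays were chosen after seeing the data, and all other alternatives before. The planned filter at 120, meant to be stricter, proved slightly looser than the median used. Array weights did not converge for the thymus and the spleen and thymus interaction and were not run there. Of the named genes past the threshold, 39 of 86 kept their call under every alternative in the tagged comparison, 34 of 58 in its interaction with untagged cells, 38 of 64 in perinate-treated and 0 of 13 in adult-treated tagged against untagged cells, 61 of 93 in the thymus and 51 of 81 in the spleen and thymus interaction. The signal over background of dim genes cannot be judged from these values, and where no cause follows from fewer genes or arrays, the cause was not tested.

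A minimum 2-fold change left 379 genes in the tagged comparison, 309 in its interaction with untagged cells, 173 and 17 for tagged against untagged cells of perinate-treated and adult-treated mice, 435 in the thymus and 344 in the spleen and thymus interaction. In the same order, array weights gave 5904, 1077, 3867 and 71 genes for the first 4. The 2 groups alone gave 3371 genes in the tagged comparison and 120 in the adult-treated mice, where all 18 arrays gave 99, quantile normalization 9, centring 12 and no filter 17. In the spleen and thymus interaction quantile normalization gave 1147 and centring 1082. The interquartile range as a covariate gave 376 in the tagged comparison (361 of them shared with the 2020), 0 in the adult-treated mice, 1462 in the spleen and thymus interaction, and 198 genes in one direction in both tissues. Leaving out both narrowest spleen arrays gave 1076, 247 and 0 in the tagged comparison, its interaction and the adult-treated mice.

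Leaving out each array in turn gave 906 to 2511 genes in the tagged comparison, 0 to 5 in the untagged one, 279 to 679 in their interaction, 299 to 1001 and 0 to 774 for tagged against untagged cells of perinate-treated and adult-treated mice, 707 to 4388 in the thymus, 393 to 1069 in the spleen and thymus interaction, and 313 to 927 for the overlap.

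With a replicate block over the 12 spleen arrays 655 genes passed in the tagged comparison (576 higher, 79 lower), 274 in its interaction and 11 in the adult-treated mice. A block over the untagged arrays, which the numbers were taken to pair, gave 49, with 692 genes at an unadjusted p under 0.05 (the block over all 12 spleen arrays gave 0 and 562). It ended the call of the stroma list and changed no other list call there. In tagged against untagged cells of perinate-treated mice, which share only numbers 4 and 5 (r of -0.11 and 0.00), the block gave 3188. That fit rests on replicates 4 and 5 of each group alone and leaves hardly any residual degrees of freedom. Its count is therefore not comparable with the 760 of the main fit. In the thymus r was -0.05, 0.06 and 0.12, not each over the bound of 0.1, so numbers were not taken to pair these arrays, and the block gave 2428. As among the untagged arrays, an array correlated best with another number, here replicate 1.

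Some results turned, most of them near 0. For a list this means that camera, which sets the list against the other genes, pointed to the other side, so a median can keep its sign. Xist in the spleen and thymus interaction ranged from -1.329 to 0.684 with each array left out, positive without perinate-tagged replicate 2. In the untagged comparison the test turned for the mitosis list (median -0.005) with no filter (-0.014) and with array weights (0.194), and for the resting Treg list with array weights (-0.033). There, with each array left out, the median of the mitosis list ranged from -0.14 to 0.221, the resting Treg list from -0.103 to 0.179, the effector Treg list from -0.122 to 0.213 and the cholesterol list from -0.014 to 0.262. The test of each turned without untagged perinate-treated replicate 3 (0.221, -0.103, 0.213 and -0.01), although the effector median, 0.036 with all arrays, kept its sign. The stroma list was 0.07 with the covariate. In adult-treated mice the interferon and immediate early lists were 0.5 and 0.073 with the block over the 12 spleen arrays. In the thymus the stroma list was 1.176 with the filter at 240 (3 genes left) and the TCR and NF-kB list -0.224 with the covariate.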

Other observations

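Of the tests in this part, those of the sex of perinate-tagged replicate 2 and of the fetal list were chosen only after the result was seen, and the test of the 50 thymus genes was planned before its result.

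Beyond the lists described so far, perinate-tagged arrays had higher transcript of single genes of T cell, B cell and metabolic lists than adult-tagged ones. Of 18 conventional CD4 T cell genes 5 were higher and 2 lower (6 and 2 adjusted over the list alone), the follicular homing receptor Cxcr5 by 1.24 ± 0.15 and the cytokine gene Il4 by 1.17 ± 0.14, while the list did not pass (adjusted p = 0.413). Of 10 NK and cytotoxic genes 3 were higher and 1 lower (5 and 1 adjusted over the list alone), the granule genes Nkg7 and Gzma by 1.86 ± 0.24 and 1.70 ± 0.26, and perforin, Prf1, by -0.60 ± 0.20 (list adjusted p = 0.117). Of 7 measured B cell genes 3 were higher (4 adjusted over the list alone), Ly86 by 1.73 ± 0.21, the class II invariant chain Cd74 by 1.34 ± 0.30 and Cd79b by 0.66 ± 0.14 (list adjusted p = 0.507). Whether these transcripts came from the Tregs was not tested. Glycolysis genes were higher in 6 of 20 cases (6 adjusted over the list alone), Pgk1 by 1.05 ± 0.13, and cholesterol synthesis genes in 4 of 18 (4 adjusted over the list alone), Ebp by 0.98 ± 0.13, with list adjusted p of 0.0727 and 0.592.

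The remaining lists held few changed genes between the tagged groups, over all genes and adjusted over the list alone, and none passed as a list. TCR and NF-kB activation had 2 of 28 higher (1 adjusted over the list alone; adjusted p = 0.929), with the cytokine gene Tnfsf11 at 0.85 ± 0.17. Immature thymocyte genes had 2 higher and 1 lower of 17 (2 and 2 adjusted over the list alone; adjusted p = 0.834), with a median of 0.09 and a test on the lower side. Ribosome biogenesis had 1 of 31 higher (1 adjusted over the list alone; adjusted p = 0.652), also with a positive median (0.08) and a test on the lower side, and ribosomal proteins had 1 of 39 lower (0 adjusted over the list alone; adjusted p = 0.0609). Stroma and epithelium genes had 3 of 15 higher (3 adjusted over the list alone; adjusted p = 0.193), with a median of -0.19 and a mean of 0.01. Erythroid genes had 0 of 6 changed (0 adjusted over the list alone; camera adjusted p = 0.409). The sex-linked list had too few measured members in the spleen fit, and in the thymus 1 of 3 was higher, Kdm5d by 0.40 ± 0.12 (1 adjusted over the list alone; adjusted p = 0.948).

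The untagged spleen arrays differed among themselves within both treatments. The first principal component of the 12 spleen arrays held 42.4% of the variance. On it untagged perinate-treated replicate 3 lay at -11.3 and untagged adult-treated replicates 3 and 4 at -12.7 and -8.2. The other untagged arrays lay between 8.1 and 12.3, the adult-tagged arrays between -28.8 and -15.3 and the perinate-tagged arrays between 15.8 and 27.7. On the second principal component of the 12 spleen arrays, which held 24.5% of the variance, replicates 4 and 5 lay at -17.4 and -19.1 in perinate-treated and at -20.8 and -18.3 in adult-treated mice, while replicate 3 lay at 6.5 and 7.4 and the tagged arrays between 5.4 and 15.1. The cholesterol transporter gene Abca1 had values of 9.60, 9.80, 9.39 and 9.85 on these 4 arrays, and 8.16 and 7.79 on both replicates 3. Abca1 was chosen here after its values were seen.

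Perinate-tagged replicate 2, labelled female, had male levels of Y-linked genes and intermediate Xist. Xist lay 2.08 above the highest of the 6 male arrays on the log2 scale, which argues against a single male mouse in place of a female. No thymus array (0 of 6) had the female pattern a swap would need. Xist stood 5.94% of the way from the male to the female mean on the linear scale. Kdm5d (8.87) and Uty (9.05) lay near the male means of 9.24 and 9.09. A sample of mostly male cells with some from females is a candidate explanation that the values fit, found and tested on the same array. No biological explanation was tested.

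Because Igf2bp3 was higher in perinate-tagged spleen Tregs and in the perinate thymus, a wider fetal programme was considered as a hypothesis. The fetal and imprinted list did not pass in the spleen (camera adjusted p = 0.815), although 4 of its 11 members were higher and fry, which does not compare the list with other genes, passed (adjusted p = 0.000829). Without Igf2bp3, the gene that prompted the hypothesis, the other 10 genes had a median of -0.03 and fry gave an unadjusted p of 0.072, so the list as a whole gives the hypothesis no support.

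A second hypothesis was that genes of perinate thymic Tregs might stay higher in cells tagged at that age. The 50 genes highest in the perinate thymus outside the DNA replication and mitosis lists, ranked with the interquartile range as a covariate, had a median of 1.36 in the spleen with the same covariate (quartiles 0.76 and 1.75). Of the 50, 47 were higher and 33 passed (42 without the covariate), and 10000 random lists had a median of -0.02 and a highest of 0.18. The random lists were matched on mean level only and not on how far genes move together, so they do not gauge the spread of a list of co-regulated genes. Many of the 50 belong to the cell cycle although outside those lists (Kif4, Ncapg, Aspm and Stil among them), so the result may largely restate the difference in division. Genes with other roles, chosen after their values were seen, were not alike. Higher in spleen were Igf2bp3 (2.19), Dsg2 (2.06), Bmpr1a (1.90), Ly86 (1.88), Slc43a1 (1.43), Fbln1 (0.96), Fosb (0.96) and Asns (0.76). Stxbp6 (0.30), Idi1 (0.48), Nedd4 (0.64), Jup (0.73), Sparc (0.29) and Xcl1 (0.76) did not pass. Neither did Tgfb3 (0.96), Hmgcs1 (0.20), Sqle (-0.07), Ryr2 (-0.16) and H2-Q4 (-0.47).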
